A study of Mus musculus with 6 samples.

How the data were processed

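The study measured polyadenylated RNA from ear skin of tamoxifen-treated mice at postnatal day 21, in 3 control and 3 lecko libraries, the groups being taken from the sample titles. The deposited table gives estimated counts per gene for the 6 libraries, a unit read from its values, of which 9.6 to 10.5% per library are not whole numbers. The submitters' processing notes name HISAT2 2.2.1, Bowtie2 2.4.5, RSEM 1.3.1 and the mouse build GRCm38.p6, and the role and order of these tools, the strand setting and the annotation are not given in the sources used here. Estimated counts divide reads among similar genes, so values of near-identical genes depend on that division: 37 genes in 17 sets held values identical to those of another gene. The labels list more than 1 tamoxifen schedule for the series, and the schedule used for these mice is not stated for this tissue.

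Total counts were 17242921 to 17825135 per library, so depth was nearly equal between groups. Of 18482 genes, 294 had no count in any library. NCBI gene identifiers were matched to a RefSeq table of the same build, where 18432 matched and 50 did not, and coordinates come from that table. Pairs of libraries within a group differed by 8.14 to 16.82 times the sampling variance (chi-square per degree of freedom), so none was counted as a duplicate. The first principal components of log2 CPM held 32.4% and 22.3% of the variance.

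Counts were rounded to whole numbers, genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left out 3626 genes, and libraries were scaled by TMM. Differences were tested with edgeR 4.0.16 (robust quasi-likelihood fit, group as the sole term) in R 4.3.3, with Benjamini-Hochberg adjustment over 14856 genes and a threshold of 0.05. Log2 CPM used a prior count of 2. Kdr relative to endothelial genes was tested by an exact two-sided permutation test over 20 arrangements, whose smallest p is 0.1.

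Of 40 gene lists fixed in advance, 37 were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists. A list needed 5 tested members: the B and plasma cell list had 3, and the mitochondrially encoded list had 0 genes in the table. The sex-linked list served as a check on the libraries through 4 Y-linked genes. List medians and means are of log2 CPM differences, lecko minus control.

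Named genes followed a fixed rule: Kdr and 11 fixed endothelial, lymphatic and blood genes, up to 10 genes in each direction that passed the threshold with a mean log2 CPM of at least 1 and no overlap between groups, leaving out unnamed gene models and sex-linked genes, and from each list described up to 4 called members or, where fewer than 2 were called, the members with the smallest p up to 2. Genes outside the rule are said to be so where they appear.

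Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors and upper-quartile factors, library size without the 50 most abundant genes, other filters, a fit without robust estimation, a fold threshold, a replicate block, sex as a covariate, leaving out each library, camera with an estimated correlation and fry. Sex was taken from Y-linked counts alone (threshold 10 CPM), because Xist was not analysed here. A fit without the 2 controls above this threshold, a correction for transcript length and GC content, and library size without skeletal muscle genes were added after seeing the data.

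The scripts were tested on simulated data for the lecko against control comparison: among 14771 genes with 200 changed, edgeR recovered 69% of those changed 1.5-fold and 91% of those changed 2-fold, with 12 false calls among 172. With 200 genes changed, the threshold lay at a larger unadjusted p than with the 3 calls of the real data. The changed genes were also drawn above a minimum CPM, so these shares do not carry over to the real data. On the same simulated counts DESeq2 made 28 false calls among 192 and limma-voom 6 among 153. In 20 simulations with no change and independent genes, camera called 0 lists.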

Results

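RNA was measured in ear skin of mice at postnatal day 21 after tamoxifen treatment. The lecko group lacked Kdr, the gene of the receptor VEGFR2, in the lymphatic endothelium, and the control group consisted of littermates. Each group held 3 libraries of polyadenylated RNA, with total estimated counts between 17242921 and 17825135 per library. Of 18482 genes listed, 14856 had enough counts to be tested. The comparison asks how the skin transcriptome, in particular lymphatic and haematopoietic genes, differs when VEGFR2 is removed from lymphatic vessels. Values are CPM, counts scaled to the size of each library, and p-values measure the spread between these 6 samples, since the labels do not name the animal or litter of each library. The tests of this comparison, the gene lists and the alternatives were chosen before the data were examined, except where a choice is said to be later.

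Counts of 4 Y-linked genes differed within the control group: controls 2 and 3 held 4272 and 4564, while control 1 held 18 and the lecko libraries held 4, 21 and 9. Libraries above and below a threshold of 10 CPM over these genes were treated as male and female. The groups thus differ in sex as well as genotype, and control 1 is the sole control that matches the lecko libraries.

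Kdr fell in the lecko skin. It gave 34.2 ± 3.81 CPM in control skin and 10.4 ± 0.732 CPM in lecko skin (SD, n = 3 each), from 566, 545 and 674 reads in controls 1 to 3 and 173, 198 and 180 reads in the lecko libraries. Kdr lies on chromosome 5 from 75932827 to 75979072 in GRCm38.p6. The log2 fold change of Kdr was -1.72 (SE 0.10), adjusted p = 0.00026 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and a loss of 69.6% of its reads (95% interval 62.8 to 75.1%). Set against the mean of 32 blood and pan-endothelial genes, log2 Kdr was 0.313 ± 0.092 in controls and -1.231 ± 0.107 in lecko libraries (SD, n = 3), a difference of -1.544 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows).

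Zfp949, a zinc finger gene, and Morf4l1b, a gene related to the chromatin factor Morf4l1, were the other genes past the threshold, both higher. Zfp949 (chromosome 9, 88548020 to 88571086) rose from 24.1 ± 2.25 to 91.1 ± 7.92 CPM (SD, n = 3 each), a log2 fold change of 1.92 (SE 0.09). Morf4l1b (chromosome 19, 41525252 to 41526961) rose from 23.0 ± 1.96 to 61.8 ± 3.04 CPM, a log2 fold change of 1.42 (SE 0.08). The adjusted p was 8.2e-05 for Zfp949 and 0.00016 for Morf4l1b by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Morf4l1b and Morf4l1 are similar in sequence, so their counts depend on how reads were split, and Morf4l1 itself was at 337.7 CPM in controls and 316.48 CPM in lecko skin. In all, 2 genes rose and 1 fell by this test, and 1272 genes (8.56%) had an unadjusted p under 0.05, 726 of them higher. DESeq2 called 22 higher and 10 lower, with the Y-linked Ddx3y and Eif2s3y among its calls. The groups did not overlap for 2169 genes (14.6%, against 10% by chance). Leaving out control 2 gave 36 genes higher, and leaving out lecko 2 gave 4 higher and 2 lower. Leaving out control 1, the control below the Y-linked threshold, gave 5 lower, which were Kdr and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, and added the X-linked Eif2s3x among 3 higher.

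**Figure D1:**
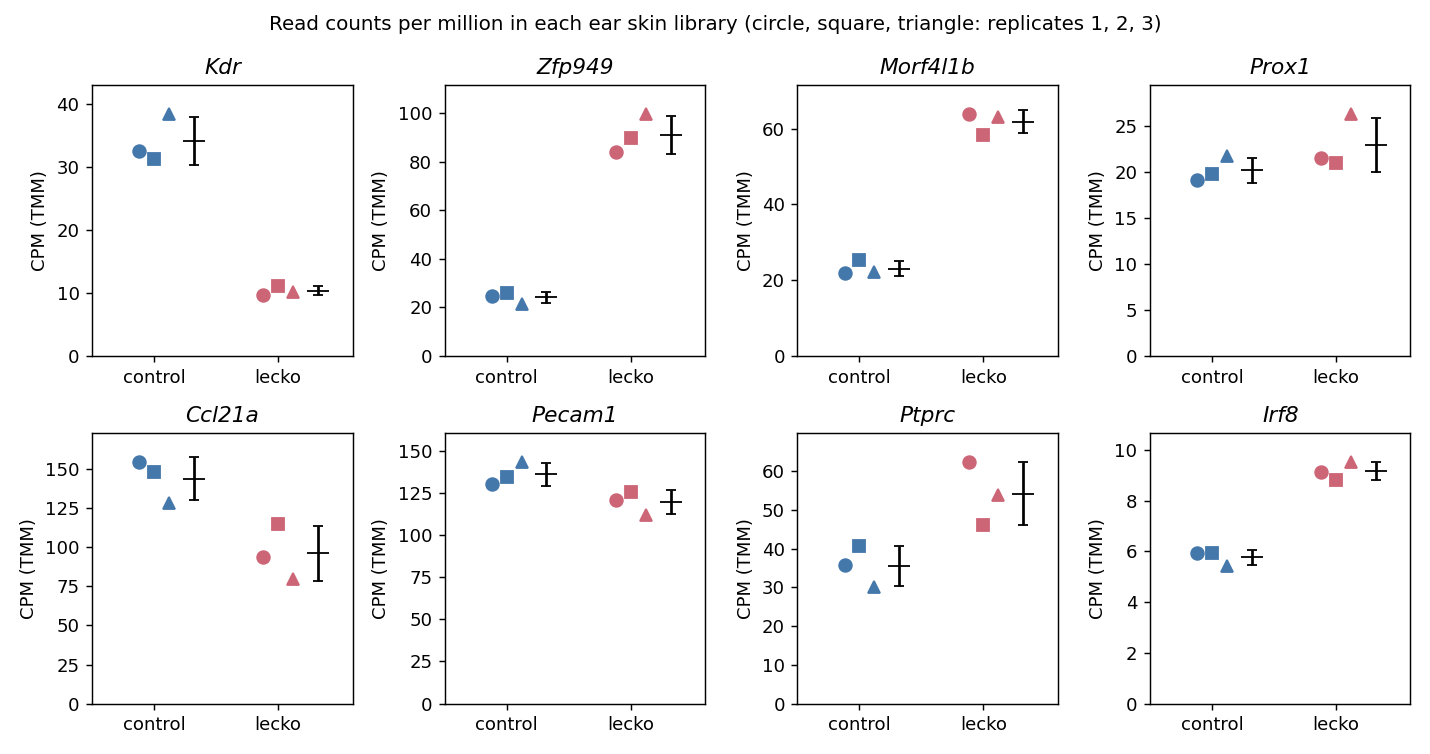
CPM after TMM scaling (vertical axis, from 0) of 8 genes in each control and lecko library, with the mean and SD (n = 3) beside the points. Kdr lies between 9.76 and 11.2 CPM in the lecko libraries and Zfp949 and Morf4l1b lie above the controls in all of them, while Prox1 overlaps between the groups.

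Genes of lymphatic identity showed no call by edgeR. Prox1, the master regulator of lymphatic fate, had a log2 fold change of 0.18, Flt4 (VEGFR3) -0.16, Lyve1 -0.10 and Pdpn 0.20. The chemokine gene Ccl21a was at 144 CPM in controls and 96.0 CPM in lecko skin, log2 -0.58, which did not pass over all genes (adjusted p = 0.42 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) or by limma-voom (0.453) but was called by DESeq2 (0.0115). Nrp2, a co-receptor of VEGFC, had a log2 fold change of 0.24. The lymphatic endothelium list had a median log2 difference of -0.10 over 19 members, 8 of them positive (camera adjusted p = 0.228). It lay between -0.09 and 0.00 with each library left out, at -0.02 without control 1, 0.00 without control 2 and -0.04 without lecko 3, and at -0.01 with sex as a covariate. The VEGF ligand and receptor list had a median of -0.01 and a mean of -0.13 (camera adjusted p = 0.761), and 2 of its 10 genes were higher and 1 lower when adjusted over the list alone, against 1 lower (Kdr) over all genes. The higher ones were Nrp2 and Vegfd (log2 0.34), Vegfd being named after its values were seen.

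Blood and pan-endothelial genes, which do not single out blood vessels, were lower as a list. Its 32 members had a median log2 difference of -0.19, 26 of them negative, among them Cldn5 (-0.46), Gpihbp1 (-0.54), Cdh5 (-0.25) and Pecam1 (-0.19). The camera adjusted p was 3.65e-08, and adjusted p = 0.271 with an estimated correlation. By edgeR, 12 members had an unadjusted p under 0.05, 9 passed when adjusted over the list alone and 0 over all genes. Pericyte and smooth muscle genes had a median of -0.23 over 16 members, with Acta2 at -0.24 and Rgs5 at -0.25, and 2 passed when adjusted over the list alone (camera adjusted p = 0.000599, and adjusted p = 0.271 with an estimated correlation). Angiogenic signalling genes had a median of -0.11 over 24 members, with Tie1 at -0.24 and Apln at -0.40 (camera adjusted p = 0.00239, and adjusted p = 0.271 with an estimated correlation). With sex as a covariate the pericyte and angiogenic lists were no longer called (camera adjusted p = 0.0617 and 0.0988), with medians of -0.15 and -0.12. The blood and pan-endothelial median was -0.12 without lecko 3, and the pericyte median -0.15 without lecko 2. Flt1 had a log2 fold change of -0.15.

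Haematopoietic genes were higher as lists, and no single member passed edgeR's test over all genes. The haematopoietic transcription factors had a median log2 difference of 0.16 over 26 members, 20 of them positive, with Irf8 at 0.67 and Ikzf1 at 0.51, and these 2 passed when adjusted over the list alone. The camera adjusted p of this list was 0.000606, and adjusted p = 0.271 with an estimated correlation. Runx1, Gata2 and Tal1, regulators of blood cell formation, had log2 fold changes of 0.21, -0.06 and 0.09. Haematopoietic progenitor markers had a median of 0.33 over 13 members, 11 of them positive (camera adjusted p = 0.00294, and adjusted p = 0.418 with an estimated correlation). Ptprc (0.61) and Cd48 (0.56) had the smallest p, and both also belong to the pan-leukocyte list. In all, 3 members passed when adjusted over the list alone. Csf3r, also in the neutrophil list, was at 0.87, and Itga2b, also in the platelet list, at -0.36. This list's difference is therefore not separate from that of the leukocyte lists.

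Leukocyte genes were higher as lists as well. All 20 pan-leukocyte genes were positive, with a median log2 difference of 0.43, 10 at an unadjusted p under 0.05 and 5 past the threshold when adjusted over the list alone. Ptprc, which encodes the leukocyte antigen CD45, was at 35.6 ± 5.23 CPM in controls and 54.2 ± 8.11 CPM in lecko skin (SD, n = 3 each), log2 0.61, and Cd48 had a log2 fold change of 0.56. The camera adjusted p was 2.18e-09, and adjusted p = 0.536 with an estimated correlation. The list's mean log2 CPM overlapped between the groups, at 4.44 in control 2 and 4.40 in lecko 2. In the same libraries this mean was 4.95 and 4.74 for macrophage and 5.1 and 5.09 for MHC class II genes. For T and NK cell genes it was 2.11 and 2.03, and for complement genes 5.81 and 5.67. The means of the dendritic and inflammatory lists did not overlap. DESeq2 called Ptprc (adjusted p = 0.0248) and Ciita (0.03), and limma-voom did not (0.454 and 0.317). The macrophage list had a median of 0.40 (Fcgr1 0.74, Cd68 0.44), the MHC class II list 0.35 (Ciita, its transactivator, 0.59, and H2-DMb2 0.58, both past the threshold when adjusted over the list alone) and the dendritic and Langerhans cell list 0.28 (Siglech 1.52, Clec10a 0.33). Their camera adjusted p-values were 2.54e-05, 5.31e-06 and 0.000446, and adjusted p = 0.579, 0.418 and 0.418 with an estimated correlation. T and NK cell genes had a median of 0.30, with Cd4 at 0.57 and Icos at 0.54 (camera adjusted p = 0.000701, and adjusted p = 0.545 with an estimated correlation), and this call ended without control 3, where the median was 0.06, and with sex as a covariate (camera adjusted p = 0.13). Complement genes had a median of 0.29, with C3 at 0.32 and C1s1 at 0.31 and 4 of 17 past the threshold when adjusted over the list alone (camera adjusted p = 5.94e-05, and adjusted p = 0.541 with an estimated correlation). Inflammatory cytokine and chemokine genes had a median of 0.28, with Ccl2 at 1.13 and Tslp at 0.79 (camera adjusted p = 0.000553, and adjusted p = 0.291 with an estimated correlation). Single libraries moved several of these medians by over 1.5 times: without control 3 they were 0.20 for macrophage, 0.20 for MHC class II and 0.14 for complement genes, and without lecko 1 they were 0.28 for pan-leukocyte, 0.25 for macrophage, 0.15 for complement, 0.17 for T and NK cell and 0.17 for inflammatory genes.

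**Figure D2:**
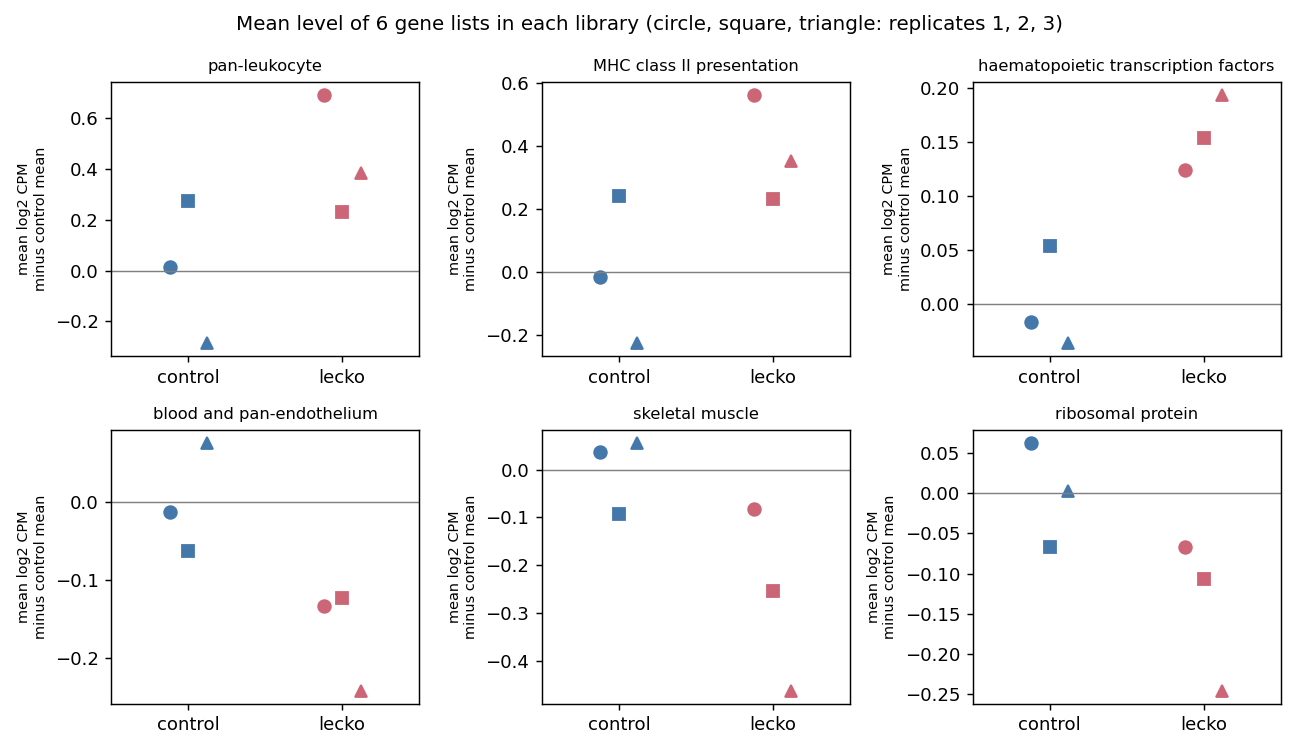
Mean log2 CPM of the members of 6 gene lists in each control and lecko library (vertical axis), less the mean of the 3 controls, with each library as a point. The pan-leukocyte points overlap between the groups, and the blood and pan-endothelium points do not.

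Other tissues of the ear also differed as lists. Skeletal muscle genes had a median log2 difference of -0.30 over 36 members, with Cacna1s at -0.30 and Ryr1 at -0.34 and 3 lower when adjusted over the list alone (camera adjusted p = 1.11e-12, and adjusted p = 0.469 with an estimated correlation). Ribosomal protein genes had a median of -0.15 over 84 members (Rpl13a -0.27, Rps2 -0.22), and oxidative phosphorylation genes -0.11 over 83 (Ndufa4l2 -0.39, Atp5d -0.23). Their camera adjusted p-values were 1.36e-18 and 1.03e-10, and adjusted p = 0.536 and 0.579 with an estimated correlation. Without lecko 3 these medians were -0.09 and -0.05, and without lecko 1 the oxidative phosphorylation median was -0.18. Basal keratinocyte genes had a median of -0.11 (Itga3 -0.26, Trp63 -0.19), hypoxia and glycolysis genes -0.12 (Ddit4 -0.29, Slc2a1 -0.20) and Schwann cell and nerve genes -0.07 (Cnp -0.14, Mal -0.13). Their camera adjusted p-values were 0.000303, 0.000684 and 0.00333, and adjusted p = 0.511, 0.541 and 0.291 with an estimated correlation. Hair shaft and inner root sheath genes had a median of 0.76 over 26 members (Tchhl1 1.65, Prr9 0.71; camera adjusted p = 0.000684, and adjusted p = 0.579 with an estimated correlation). Interferon response genes had a median of 0.35 over 29 members (Ifit2 0.64, Oasl1 1.21; camera adjusted p = 0.0335, and adjusted p = 0.822 with an estimated correlation). With sex as a covariate, the medians of the hair and interferon lists were -0.22 and -0.26. The hair median was 1.27 without control 1 and 0.28 without control 2, and the interferon median ranged from -0.06 to 0.97 over single libraries left out. The hair call also ended without control 2 or with a strict filter on low counts, and the interferon call without control 3, lecko 1 or lecko 3. Lists of endothelial-to-mesenchymal and TGF-beta genes (median 0.14, Id2 0.26, Acta2 -0.24), cartilage (0.12, Matn3 1.24, Col9a1 0.44), fibroblast and extracellular matrix (0.12, Dpp4 0.22, Pdgfra 0.23) and melanocyte genes (0.25, Mitf 0.25, Tyrp1 0.31) were also higher. Their camera adjusted p-values were 0.0204, 0.0255, 0.0298 and 0.0489, and adjusted p = 0.671, 0.705, 0.810 and 0.705 with an estimated correlation. Id2 and Matn3 passed when adjusted over the list alone. The melanocyte call ended with a replicate block (adjusted p = 0.0568 by camera), without control 3, lecko 2 or lecko 3 and without a filter on low counts. The fibroblast, cartilage and endothelial-to-mesenchymal calls each ended without control 3 or lecko 1, the fibroblast call also without control 1, and the Schwann cell call without lecko 1. Without control 3 the fibroblast, cartilage, endothelial-to-mesenchymal and melanocyte medians were 0.00, 0.05, 0.04 and 0.00, and without lecko 1 the fibroblast and cartilage medians were 0.06 and 0.02. Without control 2 the fibroblast and cartilage medians were 0.26 and 0.20, and without lecko 2 they were 0.18 and 0.21. The melanocyte median was 0.16 without lecko 3, the hypoxia median -0.21 without lecko 1 and the Schwann cell median -0.11 without lecko 2.

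**Figure D3:**
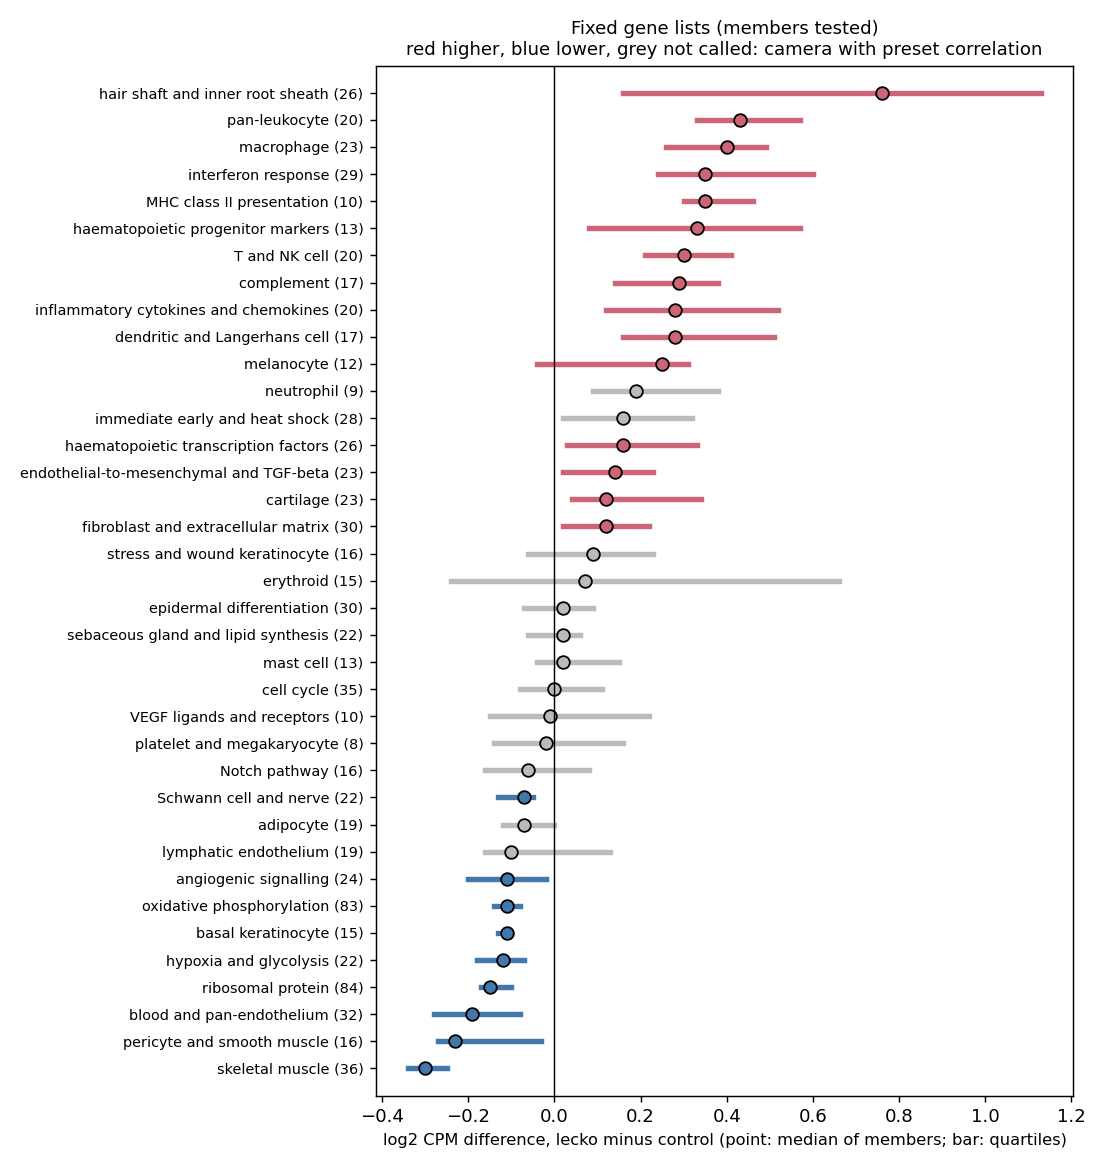
Median (point) and quartiles (bar) of the log2 CPM difference, lecko minus control, over the members of each of the 37 gene lists tested, with the number of members in brackets and colour for the camera call with preset correlation. The median was 0.76 for the hair shaft list and -0.30 for skeletal muscle.

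The remaining lists were not called by camera with all 6 libraries and the planned filter. Median log2 differences were 0.16 for immediate early and heat shock genes (Klf6 0.19, Hspa1a -0.18), 0.19 for neutrophil genes (Csf3r 0.87, Mmp9 0.37), 0.07 for erythroid genes (Ank1 -0.32, Sptb -0.28, with quartiles of -0.24 and 0.66, and 6 members higher and 3 lower at an unadjusted p under 0.05) and -0.07 for adipocyte genes (Pnpla2 -0.16, Fabp4 -0.20). They were -0.02 for platelet and megakaryocyte genes (Itga2b -0.36, P2ry12 0.37), with a mean of 0.00, and 0.02 for mast cell genes (Hpgds 0.34, Cpa3 0.14), of which Hpgds passed when adjusted over the list alone. The Notch pathway list had a median of -0.06, epidermal differentiation 0.02, stress and wound keratinocyte 0.09 and cell cycle 0.00. Sebaceous gland and lipid synthesis genes had a median of 0.02 and a mean of -0.03, and camera's direction for this list was lower. Some of these lists were called under other settings. Neutrophil genes were called higher without a filter on low counts (median 0.31, camera adjusted p = 0.0161) and without control 1 (0.51, 0.0111) or lecko 3 (0.44, 0.0416), while their median was 0.02 without control 2 (0.526), 0.12 without lecko 1 (0.456) and -0.13 with sex as a covariate. Immediate early genes were called higher without control 1 (0.15), lecko 1 (0.24) or lecko 3 (0.28) and after a length and GC correction (0.16), cell cycle genes higher without control 3 (0.12) and adipocyte genes lower without lecko 2 (-0.19). Stress and wound keratinocyte genes were called higher without control 1 (0.43, camera adjusted p = 0.0253) and lower with sex as a covariate (-0.45, 0.0103). Their median was -0.46 without the controls above the Y-linked threshold, a setting chosen after seeing the data that leaves 1 control. Sebaceous gland genes were called without lecko 2 (0.08, camera adjusted p = 0.0481). In lists for which no such count is given, 0 members passed when adjusted over the list alone by edgeR.

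In total camera with a preset correlation called 15 lists higher and 9 lower. With an estimated correlation it called 0 (smallest adjusted p = 0.271), and fry, which tests whether a set's genes move on balance in a single direction without comparing them with other genes, also called 0 (smallest adjusted p = 0.119). Its mixed test, which asks whether genes of a set change in either direction, called 6 lists. Adjusted p by this test was 0.00291 for haematopoietic transcription factors and for VEGF ligands and receptors, which include Kdr. The mixed test gave 0.00622 for pericyte, 0.0151 for blood and pan-endothelial and for MHC class II, and 0.0197 for lymphatic endothelial genes. The mean log2 CPM of 11 of the 37 tested lists did not overlap between the groups, where chance gives 10%. With sex as a covariate camera called 9 lists higher and 7 lower and kept 15 of the 24 calls, and stress and wound keratinocyte genes were newly called lower. Of the lists no longer called, interferon and hair changed sign, the angiogenic (-0.12), cartilage (0.12) and Schwann cell (-0.07) medians stayed near their values without the covariate, and the medians were -0.15 for pericyte, 0.18 for T and NK cell, 0.14 for melanocyte and 0.07 for endothelial-to-mesenchymal genes.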

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

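The alternatives without the Y-expressing controls, the length and GC correction and library size without skeletal muscle genes were chosen after seeing the data, as was the rule that a list's direction is the sign of its median and, where it is called, camera's direction. Kdr, Zfp949 and Morf4l1b were called in every setting run, Kdr with a log2 fold change between -1.78 and -1.62 when each library was left out. With each library left out, the number of genes higher ranged from 2 to 36 and lower from 1 to 5, and DESeq2 gave 22 and 10. The genes added without control 1 were sex-linked, as that leaves Y-linked counts above the threshold in every control and in no lecko library. The genes added by DESeq2 also held the Y-linked Ddx3y and Eif2s3y. For the remaining counts the cause was not tested. Lists called higher fell from 15 to 9 with sex as a covariate. With camera's estimated correlation and with fry, 0 lists were called in either direction. Both settings allow genes of a list to move together, but that is not the whole of the loss. The haematopoietic transcription factor and angiogenic lists had estimated correlations of -0.009 and -0.007, below the preset 0.01. Their unadjusted camera p still rose, from 0.000213 to 0.0144 and from 0.0011 to 0.0224. Kdr relative to Pecam1, Cdh5 and Erg alone was -1.665. Replicate numbers do not pair the samples: correlations of same-numbered libraries were 0.337, -0.072 and 0.035, and control 1 and lecko 1 were the only same-numbered libraries to match each other best. With a replicate block edgeR called 2 genes higher and 1 lower (adjusted p = 0.00383 for each with Benjamini-Hochberg adjustment) and 14 lists higher and 9 lower. Across genes, log2 fold changes correlated with GC content (Spearman -0.27) and transcript length (0.188). The change per 10-fold length was 0.155 log2 in lecko 3 and -0.097 to 0.049 in the other libraries. After the length and GC correction the ribosomal and oxidative phosphorylation lists kept at least 0.95 of their medians with their calls, so this trend is not the whole of their difference. Medians that changed sign, for which the cause was not tested, were as follows. With sex as a covariate: VEGF 0.06, platelet 0.08, neutrophil -0.13, interferon -0.26, stress keratinocyte -0.45, hair -0.22, sebaceous -0.04 and adipocyte 0.01. Without the Y-expressing controls, leaving 1 control that is assumed to vary like the lecko libraries: VEGF 0.05, platelet 0.07, neutrophil -0.10, interferon -0.27, stress keratinocyte -0.46, hair -0.23, sebaceous -0.05 and adipocyte 0.01. Cell cycle was 0.00 with DESeq2 size factors and without a filter, and -0.03 after the length and GC correction, where sebaceous was 0.00, and erythroid was -0.02 without a filter. With each library left out, values ranged from -0.07 to 0.09 for VEGF, -0.09 to 0.07 for platelet, -0.06 to 0.97 for interferon, 0.00 to 0.26 for fibroblast, -0.20 to 0.43 for stress keratinocyte, -0.06 to 0.08 for sebaceous, -0.11 to 0.12 for cell cycle, -0.12 to 0.00 for Notch, 0.00 to 0.11 for mast cell, -0.05 to 0.28 for immediate early, -0.14 to 0.12 for erythroid, -0.01 to 0.03 for epidermal differentiation and -0.19 to 0.04 for adipocyte lists. Gata2 ranged from -0.16 to 0.03 and Tal1 from -0.11 to 0.21. Over all settings, 464 of 592 list values kept their side of the threshold and their direction, 83 lost a call, 13 gained a call and 41 changed direction, some values counting under both. Of the values of the 72 named genes 1361 kept both, 0 lost a call, 4 gained a call and 2 changed sign. Depth limits genes near 1 CPM, such as Esm1 (SE 0.31). The large log2 fold changes of Siglech (SE 0.45), Tchhl1 (0.64), Oasl1 (0.61), Matn3 (0.29) and Tslp (0.26) also rest on such low counts.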

Other observations

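The genes of this paragraph were named after their values were seen, except Ccl21a, Apln, Ptprc and Ciita. All 4 adult globin genes were higher in lecko skin, Hba-a1 with a log2 fold change of 0.78, Hba-a2 0.83, Hbb-bs 0.78 and Hbb-bt 0.76, and none passed over all genes (smallest adjusted p = 0.53 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ccl21c and its copies Gm13304, Gm21541 and Gm10591, which share 1 set of values, had a log2 fold change of -0.61 beside -0.58 for Ccl21a. Esm1 and Apln, genes of sprouting endothelium, were at -0.86 and -0.40, and the lymphatic growth factor genes Vegfc and Vegfd at 0.27 and 0.34. DESeq2, unlike edgeR and limma-voom, called Ccl21a (adjusted p = 0.0115), Ptprc (0.0248) and Ciita (0.03). On simulated counts of this comparison it made 28 false calls among 192, against 12 among 172 for edgeR. Those counts were drawn with edgeR's own dispersion estimates, so these shares of false calls do not carry over to the real data.

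A first fit of the groups had been seen before the bounds of any test below were set. The tests of Kdr, of Zfp949 and Morf4l1b, and of blood left in the tissue were chosen after the result was seen. So were the condition on control 1 in the sex tests, the condition on globin genes in the blood test and the list-by-list comparison of splits. Kdr was lower by 69.6% in whole skin, although blood vessels also express it. A lower endothelial share of the tissue would lower Kdr and other endothelial genes alike, but Kdr relative to them differed by -1.544. A lower lymphatic share would lower genes limited to lymphatic endothelium by at least as much as Kdr. But the median of the lymphatic list was -0.1, between -0.09 and 0.00 with each library left out and -0.01 with sex as a covariate. That list is not limited to these cells, as it shares Lyve1 with the macrophage list. Its members ranged widely, with Ccl21a at -0.58 and Prox1 at 0.18, and 8 of 19 were positive. Whether lymphatic endothelium carried this much of the skin's Kdr, or deletion reached other cells, was not tested and needs sorted cells.

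Zfp949 and Morf4l1b could differ because the groups differ in sex, but with sex as a covariate their log2 fold changes were 1.87 and 1.5 (adjusted p = 0.021 for both by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). This rests on control 1, from which the lecko mean lay 15 and 20.8 lecko SDs away. Reads shared with Morf4l1 stay open: the summed count had a log2 fold change of 0.07 (95% interval -0.11 to 0.25), which holds both 0 and the 0.15 that an unchanged Morf4l1 would give. A variant haplotype around Zfp949, which lies on another chromosome than Kdr, also stays open: 3 of 35 neighbours within 5 Mb had an unadjusted p under 0.05, where 3 were expected. Morf4l1 lies on chromosome 9 as well, from 90091669 to 90114820, within that window. Shared reads and a haplotype are therefore not necessarily independent explanations. No sequence variant was examined.

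The higher leukocyte lists could come from sex, from blood left in the tissue or from the knockout. With sex as a covariate the pan-leukocyte, macrophage and MHC class II medians kept at least 0.88 of their size. This met the bound against sex, which was set after a first fit of the groups had been seen. But the fit with sex rests on control 1 alone, from which the lecko mean lay only 1.8, 1.5 and 2.4 lecko SDs away. Sex and genotype therefore cannot be told apart here. Blood would leave tissue-resident myeloid genes near 0, and 8 such genes differed by 0.3, just within their SD of 0.31 (exact permutation p = 0.4), but 7 of the 8 belong to the macrophage list, whose mean differed by 0.35, so this test is not independent of the pattern. Globin genes differed by 0.77 (SD 0.37), but did not follow the pan-leukocyte score within groups: in controls 1 to 3 globin was 7.49, 7.91 and 8.1 log2 CPM with scores of 4.18, 4.44 and 3.88, and in lecko 1 to 3 it was 8.17, 9.01 and 8.62 with scores of 4.86, 4.40 and 4.55. This condition, which rests on 3 libraries per group, was added after its values were seen. Without it, the bound on the resident genes was met in favour of blood. Blood left in the tissue and an effect of the knockout both stay open.

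The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 3 genes and the highest other split 4, so that 2 splits called at least as many as the real one, and the real split called 24 lists against 22 in the highest other, so that the real split is the 1 split with as many. By edgeR 1272 genes had an unadjusted p under 0.05 in the real split. The number was 1346 with controls 1 and 2 and lecko 1 against the rest, and 1421 with controls 1 and 3 and lecko 2. In the remaining splits it was 183 to 649. Every one of the 24 called lists was also called in at least 1 of the 9 other splits, each of which called 5 lists or more, and 9 of the 24 had their largest absolute median in the real split. Each other split sets 2 libraries of 1 genotype and 1 of the other against the reverse, so it keeps part of any genotype difference. A list that truly differs can therefore be called there, and these calls alone do not show variation within a genotype. The pan-leukocyte list had an absolute median of 0.43 in the real split and 0.47 when controls 1 and 3 and lecko 2 were set against the rest. The correlation between genes of a called list, as camera estimated it within groups, ran from -0.009 (haematopoietic transcription factors) to 0.948 (interferon response). It was 0.871 for pan-leukocyte genes, which thus varied together across libraries of the same genotype. For lists with so high a correlation, the camera calls with a preset correlation do not separate genotype from such variation. Near the preset 0.01 lay the haematopoietic transcription factor, angiogenic (-0.007), Schwann cell (0.018) and pericyte (0.026) lists. Their calls also ended with an estimated correlation.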
